A study of Mus musculus with 5 samples.

How the data were processed

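H2AK119ub was profiled by ChIP-seq in wild-type and in DDX5 knockout mouse embryonic stem cells, and RYBP in wild-type cells with an antibody against RYBP under its alias DEDAF, with 1 library for each. An input library of each genotype completes the 5 samples and was not analysed here. Groups were taken from the sample titles. The labels give 1 library per group and no replicate numbers.

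Per the submitters' processing notes, the tools were Bowtie2 version 2.2.5 and MACS version 1.4, and the genome build was mm10. The role of each tool, the peak threshold and the use of the input libraries as controls are not given in the sources used here. The authors' files are peak lists, 1 per library, so the peaks were called per library and not on pooled samples. Each deposited list gives chromosome, start and end, and its score column holds 0 for every peak, so no height, fold enrichment or p-value per peak was used. Read depth is unknown. A library with fewer reads or lower enrichment gives fewer and narrower peaks with no change in the chromatin, and this cannot be separated from a difference between genotypes by peak positions alone.

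Starts were converted to positions counted from 1 for printing. The number, width and covered length of the peaks were computed for each list. Peaks were called overlapping when they shared at least 1 bp. Shares are given with Wilson intervals at 95% and differences of shares with Newcombe intervals, and both treat peaks or genes as independent counts. Chance overlap was taken from 100 shuffles of peak positions within each chromosome between its first and last annotated gene, and from 100 shuffles that moved each peak to the same distance from another gene end of its chromosome. For the retained share, wild-type H2AK119ub peaks were split into 4 classes of equal size by width, and the difference between peaks with and without RYBP was averaged over the classes.

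Genes came from the RefSeq table of GRCm38.p6, whose coordinates are those of mm10, with 49554 genes on chromosomes 1 to 19 and X, of which 21631 are protein-coding. The table used here has no strand and no exons, and no genome sequence was used. A gene was called marked when a peak overlapped the 2 kb on either side of its start or its end, so a peak at the far end of a gene counts as well as one at its promoter. Where 2 genes lie close together, 1 peak can mark both. The covered length at a gene cannot exceed the span of its windows, which is smaller for short genes. Peak centres were classed as within 2 kb of a gene end, inside a gene or between genes, with the same count after moving peaks by 100 kb as background.

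The design set out before the data were examined was changed in 5 places. Windows at both gene ends replaced promoters, covered base pairs replaced peak scores for ranking genes, and width classes replaced score classes. Random lists were matched on decile of gene length in place of CpG content, and shuffles did not exclude assembly gaps. The planned motif counts in RYBP peaks were not run.

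The 12 gene lists were fixed before the data were examined: Hox, neural ectoderm, mesoderm, endoderm, trophectoderm, signalling, pluripotency, Polycomb subunits, germline, housekeeping, fibroblast and feeder, and imprinted genes. Of 380 distinct genes, 377 were matched to a protein-coding gene. The number of marked members is given with its percentile among 10000 random lists of the same size, which describes these libraries and is no test between genotypes. The retained number was set against random lists of wild-type-marked genes matched on decile of covered length. Neighbouring genes such as those of a Hox cluster share peaks, so members are not independent.

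The genes named were chosen by a rule whose classes and numbers were fixed before the data were examined. Its ranking by covered sequence, its windows at both gene ends and its order of ties were set later. Ddx5 and Rybp were always named. Predicted genes were left out, and the rule took the 8 genes with the most covered sequence among those marked in the wild type alone, the 8 among those in the knockout alone, the 5 among those in both and the 8 with the most RYBP, with ties in alphabetical order. In each list it took up to 3 members per class and up to 3 with RYBP. A few genes the rule took are not reported here. Yaf2, Pou5f1, Nanog, Sox2, Hoxc13, the widest peaks, the pooling of the 6 developmental lists, the Hox clusters, the comparison by chromosome and the gene families and microRNAs among the closing observations were chosen after values had been seen.

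The alternatives set out beforehand were an overlap of at least 50% of the peak, merging of peaks within 2 kb, windows of 1 kb and 5 kb, autosomes alone and unmatched random lists. Chosen after seeing the data were peaks of at least 1 kb, equal numbers of the widest H2AK119ub peaks, all peaks without chromosome 6 or without chromosomes 6 and 8, and windows over the whole gene. The scripts were tested on simulated data drawn on the 21631 genes. They gave the right class to 800 of 800 genes with simulated peaks and found 9700 of 9700 copied peaks. Of 100 lists of random genes, 1 lay at or above the 97.5 percentile and 1 at or below the 2.5 percentile, and of 100 lists with marked members planted, 100 lay at or above the 97.5 percentile. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.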

Results

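Mouse embryonic stem cells with and without DDX5, a DEAD-box RNA helicase, were profiled by chromatin immunoprecipitation and sequencing (ChIP-seq). The cells were of the line MPI-II, grown on feeder cells with LIF and inhibitors of MEK and GSK3, and the knockout was a monoclonal line made with a Cas9 nickase and paired guides in exon 2 of Ddx5. H2AK119ub, the ubiquitin mark that Polycomb repressive complex 1 places on histone H2A, was profiled in both genotypes. RYBP, a subunit of the variant forms of that complex, was profiled in wild-type cells. Each of these 3 groups had 1 library, so no difference between them has a replicate check and no p-value is given. The 2 input libraries were not analysed here. The peak lists held positions only, so the read depth of each library is unknown, and the intervals given are 95% intervals that cover counting error only. Coordinates are those of mm10, counted from 1.

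The targeted gene was examined first. Ddx5 (gene ID 13207, chromosome 11, 106780355 to 106789185) had no H2AK119ub peak within 2 kb of either end in either genotype and had a RYBP peak in wild-type cells, from 106787415 to 106789703, a width of 2289 bp. A peak list gives no expression level, so these values do not check the genotype labels. Rybp itself (gene ID 56353, chromosome 6, 100228565 to 100287358) had H2AK119ub peaks in both genotypes, 1300 bp wide in the wild type and 2329 bp wide in the knockout, and a RYBP peak of 2115 bp. Rybp lies in a part of chromosome 6, from 100 to 110 Mb, where the mark covered 3.37 times the wild-type length in the knockout. Over all of chromosome 6 this ratio, which also counts added peaks, was 1.36. Peaks of chromosome 6 with RYBP that paired uniquely between genotypes had a median ratio of knockout to wild-type width of 1.06. The spread of single peaks around that median was not examined, so the wider knockout peak is not shown to be specific to Rybp. The Rybp paralog Yaf2 on chromosome 15 also had peaks in all 3 libraries. Its H2AK119ub peaks were 1219 bp wide in the wild type and 1720 bp wide in the knockout. The ratio of covered length was 0.84 for chromosome 15 and 0.99 for its part from 90 to 100 Mb, where Yaf2 lies. Uniquely paired peaks with RYBP on chromosome 15 had a median width ratio of 0.89.

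The first comparison asked where H2AK119ub lay in wild-type and in DDX5-deficient cells. The mark covered 30.6 Mb in the knockout library and 45.9 Mb in the wild-type library, that is 66.6% of the wild-type length, in 20994 against 24235 peaks. Of 168 genes of the Hox, germ layer, trophectoderm and signalling lists marked in the wild type, 160 were marked in both genotypes, 95.2% (Wilson interval 90.9% to 97.6%), where random sets of wild-type-marked genes of like covered length gave a mean of 89.1%. Across all protein-coding genes marked in the wild type that share was 70.5% (69.3% to 71.8%), or 3706 of 5254. Marks present in the knockout alone were fewer, at 603 genes, than marks present in the wild type alone, at 1548 genes. With peaks of at least 1 kb these counts were 306 and 1664. Chromosome 6, which had more covered length in the knockout than in the wild type, unlike every other chromosome, held 59 of the 603 genes marked in the knockout alone, 9.78% (7.66% to 12.4%), against 44 of the 1548 marked in the wild type alone, 2.84% (2.12% to 3.79%). It held 5.21% of all genes tested. With peaks of at least 1 kb it held 54 of the 306, 17.6% (13.8% to 22.3%). Knockout peaks had a median width of 1417.5 bp on chromosome 6, against 935 to 1167.5 bp on the autosomes other than 6 and 8. A minimum width thus favours chromosome 6, and the higher share is no separate check.

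Knockout peaks were narrower, with a median width of 1083 bp (quartiles 802 and 1619 bp) against 1360 bp (1010 and 2063 bp). Of the wild-type peaks, 11862 overlapped a knockout peak by at least 1 bp, 48.9% (48.3% to 49.6%), against a mean of 3.49% when knockout peaks were shuffled within chromosomes and 8.46% when they were moved to the same distance from another gene. Of the knockout peaks, 13955 overlapped a wild-type peak, 66.5% (65.8% to 67.1%), against 4.05% and 9.46%. Wild-type peaks with a knockout counterpart had a median width of 1851 bp, and those without one 1120 bp. Measured in base pairs, 21.1 Mb carried the mark in both libraries, 24.8 Mb in the wild type alone and 9.47 Mb in the knockout alone. The placement relative to genes was close in both genotypes: 24.4% (23.8% to 24.9%) of wild-type peak centres and 24.9% (24.3% to 25.5%) of knockout peak centres lay within 2 kb of a gene end, against 12.3% and 11.9% after moving the peaks by 100 kb. A further 45.6% and 45.5% lay inside genes and 30.1% and 29.6% between genes.

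The widest domains of both libraries included Hox clusters. The widest wild-type peak, 39824 bp from 96278905 to 96318728 on chromosome 11, ran over Hoxb3 to Hoxb8, and knockout peaks covered 39223 bp of it. The next, 37272 bp from 143411179 to 143448450 on chromosome 7, overlapped Kcnq1, an imprinted potassium channel gene, and knockout peaks covered 30911 bp of it. The widest knockout peak, 26490 bp from 52228286 to 52254775 on chromosome 6, ran over Hoxa10 and Hoxa11. The next knockout peak, 21706 bp on chromosome 6, lay at Cyp26b1, a gene for an enzyme that degrades retinoic acid. H2AK119ub covered 87.5% of the Hoxa cluster in the wild type and 89.0% in the knockout, 58.1% and 53.3% of Hoxb, 67.9% and 43.5% of Hoxc, and 71.3% and 61.8% of Hoxd.

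**Figure D1:**
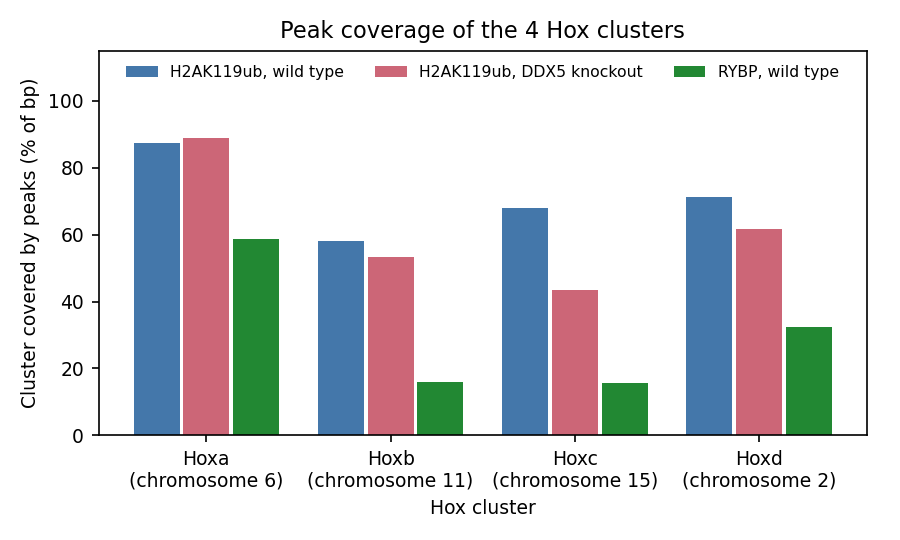
Share of each Hox cluster, in percent of base pairs from the first to the last Hox gene, covered by H2AK119ub peaks of the wild type, H2AK119ub peaks of the DDX5 knockout and RYBP peaks of the wild type, 1 library each. Hoxa, on chromosome 6, was covered alike in both genotypes (87.5% and 89.0%), and Hoxc had the widest gap (67.9% and 43.5%).

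Among genes marked in the wild type alone, those with the most covered sequence within 2 kb of their ends were Nfatc2 (5854 bp), Phf24 (5803 bp), Grina (5394 bp), Fam89a (5341 bp), Insl3 (5326 bp), Sds (4938 bp), BC034090 (4857 bp) and Ppfia3 (4810 bp). Nfatc2 (chromosome 2, 168476410 to 168601657) encodes a calcium-regulated transcription factor, and Insl3 (chromosome 8, 71689252 to 71690577) encodes a peptide hormone of Leydig cells. Insl3 also had 4370 bp of RYBP, Fam89a 2021 bp, BC034090 2461 bp, Nfatc2 1145 bp and Ppfia3 1123 bp, while Phf24, Grina and Sds had no RYBP peak.

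Among genes marked in the knockout alone, the most covered were Htra2 (5053 bp), Il17c (4169 bp), Arhgef37 (3759 bp), Krt5 (3509 bp), Id3 (3428 bp), Frat1 (3357 bp), Agt (3253 bp) and Sh2d6 (3225 bp). Htra2 (chromosome 6, 83051266 to 83054571) encodes a mitochondrial protease, Krt5 (chromosome 15, 101707069 to 101712905) the keratin of basal keratinocytes, and Id3 (chromosome 4, 136143822 to 136145392) an inhibitor of basic helix-loop-helix transcription factors. Htra2 and Sh2d6 lie on chromosome 6, and Il17c and Agt on chromosome 8, where peaks were wider than elsewhere in all 3 libraries. RYBP was present at Htra2, Arhgef37, Id3, Frat1 and Sh2d6 and had no peak at Il17c, Krt5 or Agt. Among genes marked in both genotypes with the longest covered length in the wild type, 8000 bp, the first 5 in alphabetical order were Aqp2, the water channel gene of the kidney collecting duct (8000 bp in the wild type and 7371 bp in the knockout), Asic4 (8000 and 7220 bp), Aspg (8000 and 5067 bp), Atp2c2 (8000 and 7110 bp) and Cdh22 (8000 and 7571 bp).

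Hox genes, which specify position along the body axis, were marked at 38 of 39 members in both genotypes, and Hoxc13 had no peak in either. The covered length at the ends of the 39 genes was 0.90 times the wild-type length, and 0.86 times without the 11 members on chromosome 6. Hoxa10 was covered over 8000 bp in both libraries, Hoxb6 over 8000 and 7993 bp, and Hoxb3 over 8000 and 7782 bp. The windows of a gene hold at most 8000 bp, and less for short genes. A gene covered in full in both libraries, such as Hoxa10, therefore cannot show a difference beyond its windows. This limit also bears on the ratios of covered length over lists and on rankings by covered length. Regulators of the neural ectoderm were marked at 38 of 38 members in the wild type and 37 in the knockout. Six3, a forebrain and eye regulator, had 8000 bp in the wild type and 7540 bp in the knockout, Nkx2-1 had 7616 and 6544 bp, and Barhl2 had 7587 and 4549 bp.

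Mesoderm regulators were marked at 31 of 37 members in the wild type and 29 in the knockout. The myogenic factor Myf5 (707 bp) and Tbx18 (1219 bp) were marked in the wild type alone, and Evx1 had 8000 bp in both libraries, Osr1 7846 and 7713 bp, and Foxf1 7621 and 7666 bp. Evx1 lies on chromosome 6 and Foxf1 on chromosome 8. Endoderm regulators were marked at 17 of 23 members and 16 in the knockout, with Foxa3 (1273 bp) in the wild type alone, and the pancreatic regulator Pdx1 had 7786 and 5297 bp, Nkx2-3 7448 and 7283 bp, and Foxa2 7229 and 6596 bp. Trophectoderm genes were marked at 12 of 16 and 11 members. Esx1 (825 bp) was marked in the wild type alone, and Dlx3 had 7846 and 7306 bp, Cdx2 7499 and 7241 bp, and Hand1 7435 bp in both. Genes of Wnt, BMP, FGF and related signals were marked at 33 of 37 and 30 members, with Vegfa (4026 bp), Pdgfa (492 bp) and Chrd (34 bp) in the wild type alone and with Fgf8 (7809 and 7518 bp), Wnt7b (7638 and 7568 bp) and Wnt1 (7564 and 6686 bp) among those marked in both. No member of these 6 lists was marked in the knockout alone, except that 1 mesoderm member was with peaks of at least 1 kb and with equal numbers of the widest peaks. With either of these settings, 29 mesoderm members and 11 trophectoderm members were marked in each genotype.

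Counts of marked members lay at or above the 99.99 percentile of 10000 random lists of the same size and gene length in both genotypes for these 6 lists. Set against wild-type-marked genes of like covered length, the 160 retained genes of the 6 lists together compared with a random mean of 149.6 (143 to 156 in 95% of random sets), at the 99.95 percentile. The random sets draw genes singly, so their range makes no allowance for neighbouring Hox genes that share peaks. The pooling of the 6 lists was chosen after values had been seen. No single list passed the 97.5 percentile: neural ectoderm lay at 94.7, signalling at 92.9, endoderm at 87.9 and mesoderm at 83.8. Hox and trophectoderm genes were not able to pass it, since retention of every marked member would have placed them at 90.5 and 94.3.

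Pluripotency genes did not stand apart from random lists, with the mark at 7 of 32 members in the wild type (percentile 30.1) and 5 in the knockout (percentile 22.5). Pou5f1, Nanog and Sox2, the core transcription factors of embryonic stem cells, had no peak of H2AK119ub or RYBP within 2 kb of their ends in any library. Esrrb (1983 bp), Lefty1 (1560 bp) and Dppa3 (1448 bp, on chromosome 6) were marked in the wild type alone, and Fgf4 (830 bp) in the knockout alone. Dnmt3l had 2624 bp in the wild type and 1265 bp in the knockout, Utf1 1698 and 959 bp, and Lin28a 1268 and 768 bp. The covered length over the list was 0.47 times that of the wild type, and the 4 of 7 marked members retained lay at the 41.6 percentile of genes of like covered length. With peaks of at least 1 kb, 2 members were marked in the knockout and 0 in the knockout alone, and with windows of 1 kb, 2 were marked in the knockout alone. Housekeeping genes were nearly free of the mark, at 1 of 36 members in the wild type (percentile 0.005) and 3 in the knockout (percentile 1.60, or 3.29 among random lists not matched on gene length). B2m was marked in both, and Polr2b (1645 bp) and Tubb5 (1010 bp) in the knockout alone.

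Germline genes, whose promoters are targets of a variant Polycomb complex in embryonic stem cells, were marked at 19 of 32 members in the wild type and 14 in the knockout. Majin (3163 bp), Slc25a31 (1966 bp), Mael (1810 bp) and 3 other members were marked in the wild type alone, which placed the number of such members, 6, at the 98.7 percentile of random lists, and Sycp1 (1585 bp) was marked in the knockout alone. The number marked in the knockout alone was 1 to 3 across the alternatives run. The covered length over the list was 0.65 times that of the wild type. Against wild-type-marked genes of like covered length, the number retained lay at the 43.1 percentile. Mei1 (5595 and 4401 bp), Syce3 (5490 and 3731 bp) and Tdrd1 (4214 and 3388 bp) were marked in both. Genes for Polycomb subunits were marked at 16 of 37 members in the wild type and 14 in the knockout, with Phf1 (1152 bp), Bcorl1 (814 bp) and Ring1 (752 bp) in the wild type alone and Kdm2b (1141 bp), whose product recruits a variant complex to CpG islands, in the knockout alone. With windows over the whole gene 0 Polycomb members were marked in the knockout alone, and with windows of 1 kb 3 were. Cbx8 (7359 and 7687 bp) and Cbx2 (3757 and 2863 bp), both on chromosome 11, were marked in both.

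Imprinted genes were marked at the same 13 of 27 members in both genotypes, among them Kcnq1 (8000 and 7990 bp), Igf2 (7170 and 5278 bp) and Slc22a18 (6804 and 4396 bp). Genes of fibroblasts, the cell type of most feeder layers, were marked at 10 of 24 members in the wild type (percentile 95.7) and 8 in the knockout (percentile 92.4), with Col6a1 (1687 bp) and Cd44 (1124 bp) in the wild type alone and Col1a1 (5072 and 3319 bp), Pdgfrb (4608 and 3287 bp) and Thy1 (4113 and 2389 bp) in both.

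**Figure D2:**
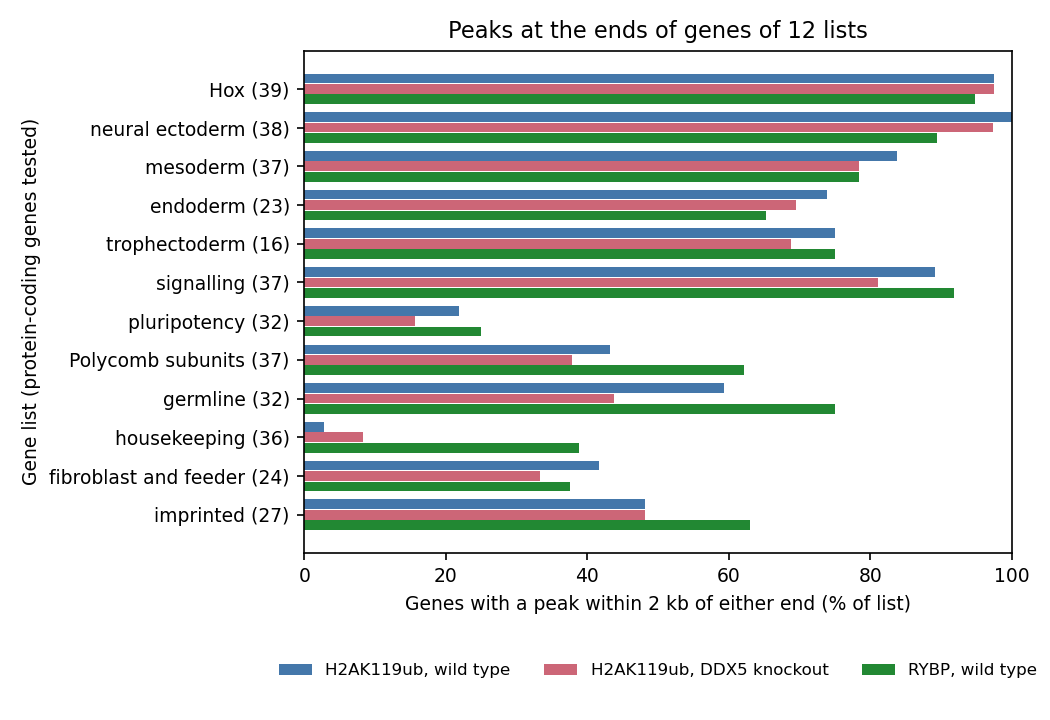
Share of the genes of 12 lists, in percent of the protein-coding genes tested (number in brackets), with a peak within 2 kb of either end, for H2AK119ub in the wild type, H2AK119ub in the DDX5 knockout and RYBP in the wild type, 1 library each. Hox, neural ectoderm, mesoderm and signalling genes were marked at most members in both genotypes, and housekeeping genes at 1 of 36 in the wild type and 3 in the knockout.

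The knockout library held fewer H2AK119ub peaks and less covered length on most chromosomes but not on chromosome 6. There it held 1754 peaks against 1239, a ratio of 1.42, and the ratio of covered length was 1.36. On the other 18 autosomes the ratio of covered length lay between 0.52 and 0.84. Each of the 11 windows of 10 Mb on chromosome 6 with at least 20 wild-type peaks lay above the median window of the genome (0.65), between 0.98 and 3.37. At the ends of protein-coding genes the ratio of covered length was 1.16 on chromosome 6 and 0.66 elsewhere. Chromosome 8 had the widest peaks of any chromosome in all 3 libraries, with medians of 1803 bp for wild-type H2AK119ub, 1443 bp for knockout H2AK119ub and 2046 bp for RYBP. Over its first 50 Mb the ratio of covered length was 0.27, and 45 of 79 genes marked in the wild type were marked in the knockout. Over the rest of that chromosome the ratio was 0.70, and 268 of 345 were.

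**Figure D3:**
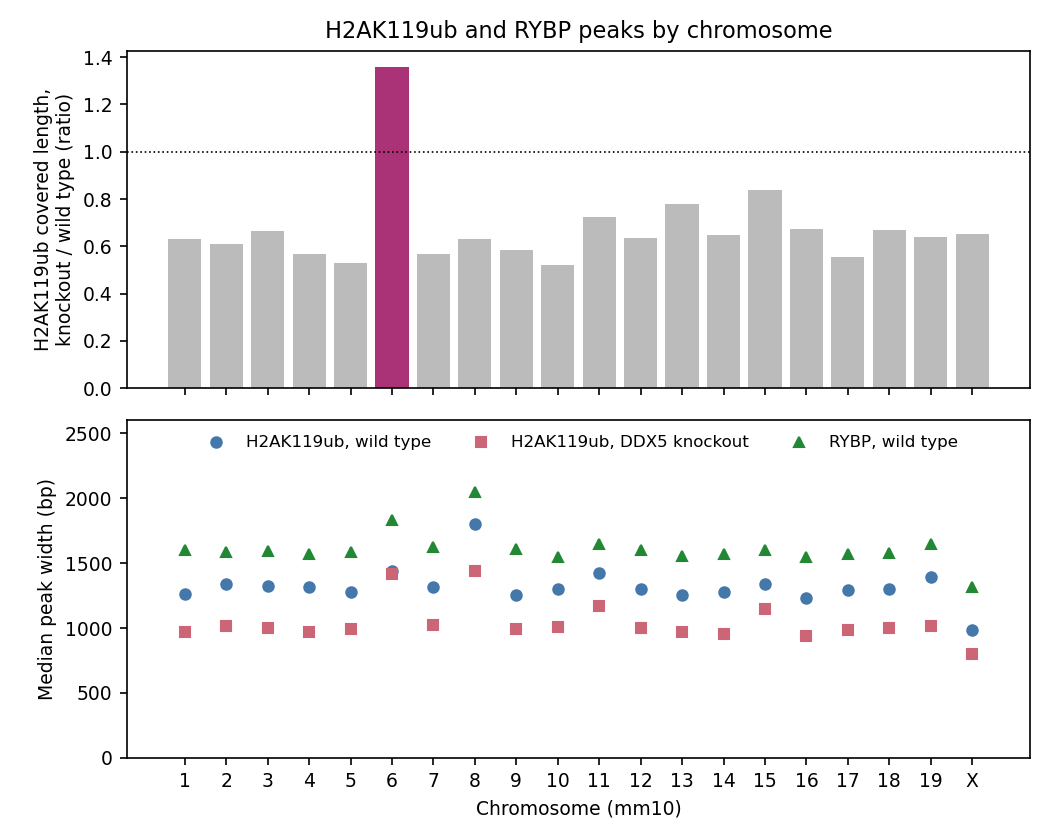
Upper panel, ratio of the length covered by H2AK119ub peaks in the DDX5 knockout to that in the wild type for each chromosome, with a dotted line at a ratio of 1. Lower panel, median width in bp of the peaks of each library on each chromosome. Chromosome 6 had the only ratio above 1 (1.36), and chromosome 8 had the widest peaks in each library.

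The second comparison asked where RYBP lay in wild-type cells and how often it coincided with the mark. RYBP peaks gathered at gene ends: 67.6% (66.6% to 68.5%) of the 9564 peaks were centred within 2 kb of a gene end, against 12.1% after moving them by 100 kb and 24.4% of wild-type H2AK119ub peaks. RYBP was present at 37 of 39 Hox genes, 34 of 38 neural, 29 of 37 mesoderm, 15 of 23 endoderm, 12 of 16 trophectoderm and 34 of 37 signalling genes. It was also present at genes without the mark: of 7399 protein-coding genes with RYBP at an end, 3527 had no H2AK119ub there in either genotype, 47.7% (46.5% to 48.8%). Housekeeping genes were an example, with RYBP at 14 of 36 members (percentile 76.1), of which 12 had no H2AK119ub peak in either genotype.

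Of the RYBP peaks, 4436 overlapped a wild-type H2AK119ub peak, 46.4% (45.4% to 47.4%), against 3.54% for shuffled RYBP peaks and 12.4% for RYBP peaks moved to the same distance from another gene. With knockout H2AK119ub the overlap was 3844 peaks, 40.2% (39.2% to 41.2%), against 2.66% and 9.40%. RYBP peaks within the wild-type mark had a median width of 1883 bp, and those outside it 1489 bp. The median over all RYBP peaks was 1634 bp (quartiles 1308 and 2083 bp). In the reverse direction, 5286 of the 24235 wild-type H2AK119ub peaks overlapped RYBP, 21.8% (21.3% to 22.3%).

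The widest RYBP peaks lay at Foxc2 (8902 bp, chromosome 8, 121112865 to 121121766), Foxf1 with the noncoding Fendrr (8578 bp, chromosome 8, 121078523 to 121087100) and Gata2 (8345 bp, chromosome 6, 88193208 to 88201552), all regulators of mesoderm or blood. Genes with the most RYBP within 2 kb of their ends were Zfp423 (7334 bp), Zfp503 (7326 bp), Hoxa6 (7284 bp), Otx1 (7124 bp), Ssbp4 (7047 bp), Dmrta2 (6917 bp), Hoxa11 (6881 bp) and Foxf1 (6746 bp), of which 5 of 8 lie on chromosome 6 or 8. Other leading members were Hoxa9 (6602 bp) among Hox genes, Irx3 (6634 bp) and Sox1 (4600 bp) among neural genes, Foxc2 (6725 bp) and Tbx2 (6239 bp) among mesoderm genes, Nkx2-3 (6592 bp) and Gata6 (4000 bp) among endoderm genes, and Gdf7 (5346 bp) among signals. RYBP was at 24 of 32 germline genes, including Zcwpw1 (3483 bp), Smc1b (2399 bp) and Tdrkh (2282 bp), and at 23 of 37 Polycomb genes, including Cbx8 (6408 bp) and the methyltransferase gene Ezh2 (2543 bp), which had no H2AK119ub peak. It was at 17 of 27 imprinted genes, including Grb10 (3158 bp) and Cdkn1c (2775 bp), at 8 of 32 pluripotency genes, including Sall1 (3633 bp) and Tbx3 (2329 bp), and at 9 of 24 fibroblast genes, including Twist2 (3210 bp) and Fbn1 (3107 bp).

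The third comparison asked whether wild-type H2AK119ub sites occupied by RYBP were the ones that carried the mark in DDX5-deficient cells. Sites with RYBP carried it more often: 3999 of 5286 wild-type H2AK119ub peaks with RYBP overlapped a knockout peak, 75.7% (74.5% to 76.8%), against 7863 of 18949 without RYBP, 41.5% (40.8% to 42.2%). The difference was 34.2 percentage points (Newcombe interval 32.8 to 35.5). At genes the order was the same, with 77.5% (76.1% to 78.9%) of marked genes with RYBP retained against 55.9% (53.5% to 58.3%) of those without. RYBP was present at 74.4% of genes marked in both genotypes, 51.6% of those marked in the wild type alone, 52.6% of those marked in the knockout alone and 22.4% of unmarked genes.

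Peaks with RYBP were wider, with a median of 2016 bp against 1250 bp, and wide peaks were retained more often with or without RYBP, so the comparison was repeated within 4 width classes of equal size. From the narrowest to the widest, peaks with RYBP were retained at 35.8%, 52.2%, 71.9% and 93.3%, and peaks without it at 21.1%, 32.6%, 47.9% and 78.4%. The difference was 14.7, 19.6, 24.0 and 14.9 points, and its mean over the 4 classes was 18.3 points (16.7 to 19.9). Within width classes the difference was thus smaller than the pooled one. RYBP was profiled in the wild type alone, so its occupancy in DDX5-deficient cells is outside these values.

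**Figure D4:**
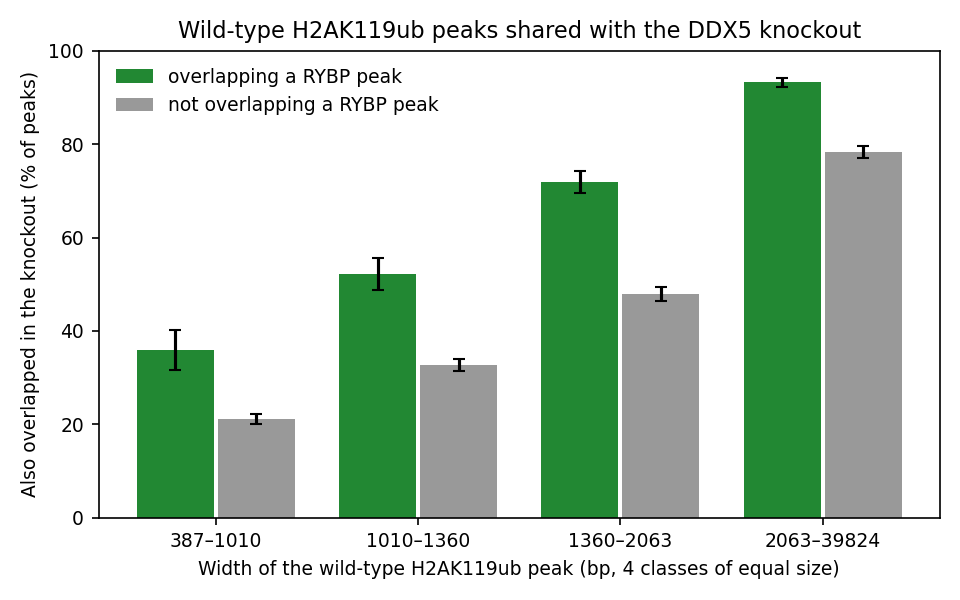
Share of wild-type H2AK119ub peaks, in percent, that overlapped an H2AK119ub peak of the DDX5 knockout, by class of wild-type peak width in bp (4 classes of equal size) and by overlap with a wild-type RYBP peak, with Wilson 95% intervals for counting error as error bars. Peaks with RYBP were retained more often in each class, from 35.8% against 21.1% in the narrowest to 93.3% against 78.4% in the widest.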

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

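The pooled difference in retained share between peaks with and without RYBP, and that within width classes, kept their sign under the alternatives run. The other values are shares, ratios and counts, which cannot change sign. Of the values that answer a comparison, 79 stayed within their interval, or within 1.5 times for a count of genes or for the knockout peak number and covered length relative to the wild type, and 30 moved. At least 3 of the 79 could not move, since the setting left their lists of peaks as they were. Of the values for single lists, 407 stayed, 260 of them at the same number, and 13 moved, most of them counts of 3 or fewer members. Equal numbers of peaks fix the ratio of peak numbers, which has no value there. With an overlap of at least 50% of the peak, the share of wild-type H2AK119ub peaks shared with the knockout was 36.8%, of knockout peaks shared with the wild type 60.8%, of RYBP peaks within the wild-type mark 32.9% and within the knockout mark 26.9%, and the retained share differed by 30.3 points pooled and 23.9 points within width classes between peaks with and without RYBP. With peaks merged within 2 kb, knockout peaks were shared at 62.0%, RYBP peaks at 45.1% and 39.1%, and the pooled difference was 41.3 points. The share of genes retained was 67.3% with windows of 1 kb and 73.4% with windows of 5 kb. The remaining alternatives were chosen after the data were seen. With peaks of at least 1 kb, the wild-type share was 44.4%, the knockout share 77.7%, the RYBP shares 44.8% and 35.5%, the difference within width classes 21.7 points, the genes marked in the knockout alone 306 and the share of genes retained 64.6%, and the knockout held 64.1% of the wild-type peak number and 57.6% of its covered length. With equal numbers of the widest H2AK119ub peaks these were 53.7% for the wild type, 64.2% for the knockout, 44.8% for RYBP within the wild-type mark, 31.8 points for the pooled difference and 73.3% for genes retained. Without chromosome 6, the wild-type share was 47.9% and the knockout share 68.1%. Without chromosomes 6 and 8, the wild-type share was 47.5% and the RYBP shares 45.3% and 38.9%. With windows over the whole gene, 74.1% of marked genes were retained. The cause of these shifts was not tested, except that a stricter overlap or fewer peaks can only lower a share of overlapping peaks taken over the same peaks. Not run were the planned minimum peak score of 100, the equal numbers by score, transcript start sites, CpG matching and motif counts. No paired analysis was possible because each group has 1 library. The unknown depth limits every difference in number and width between the 2 H2AK119ub libraries.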

Other observations

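Families of genes, some of which hold a few members of the fixed lists, differed in how the mark and RYBP fell on them. Among 117 families of at least 20 genes, keratin genes had H2AK119ub at 29 of 53 members in the wild type and 30 in the knockout, both at or above the 99.98 percentile of random lists of like gene length, with RYBP at only 4 members. Collagen genes had the mark at 23 of 44 and 20 members, semaphorin genes, which encode guidance signals of axons, at 12 of 20 and 14 members, and cadherin genes at 12 of 23 and 11 members. Protocadherin beta genes, clustered neuronal adhesion genes, had it at 12 of 22 members in the wild type and 4 in the knockout, with 8 members in the wild type alone (percentile 99.98). RYBP without the mark was found at 20 of 38 centrosomal Cep genes (percentile 99.99), 14 of 36 Ddx helicase genes (percentile 99.9), 18 of 55 Eif translation factor genes (percentile 99.8) and 10 of 21 nucleoporin genes (percentile 99.5). It was found at a smaller share of some other families, such as 11 of 49 Mrpl genes (percentile 97.7), 9 of 44 Rps genes (percentile 95.7), 6 of 53 Rpl genes (percentile 70.8) and 6 of 30 Mediator genes (percentile 66.5). Dusp genes, which encode phosphatases that act on MAP kinases, had RYBP at 17 of 24 members. Of 1110 olfactory receptor genes, 6 had the mark in the wild type and 1 had RYBP. Families are named by the stem of their symbols, members often lie in clusters that share peaks, and the families given were chosen from all 117 after their values were seen.

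The Hox-embedded microRNA genes Mir10a, Mir10b, Mir196a-2 and Mir196b had H2AK119ub in both genotypes and RYBP. Mir196a-1 had none of these. Of 22 microRNA genes of differentiated lineages, 11 had the mark in the wild type and 7 in the knockout. Mir9-3 was covered over 4090 bp in both and Mir124a-3 over 3485 and 3234 bp, while Mir143 and Mir145a, neighbours on chromosome 18 that share a peak, had 1152 bp in the wild type and no peak in the knockout. The 9 genes of the clusters with miR-125, let-7 and miR-99 family members, and 10 microRNA genes of the miR-290 and miR-302 clusters of embryonic stem cells, had no peak of H2AK119ub or RYBP within 2 kb. MicroRNA genes are annotated at short lengths, such as 65 bp for Mir99a and 71 bp for Mir125b-2. The windows around them need not reach the start of their transcripts. Over all 1228 microRNA genes, 214 had the mark in the wild type, 155 in the knockout and 133 had RYBP.

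Of the tests below, the one of selective loss at RYBP sites was chosen after its result was seen, and so was the boundary at 50 Mb on chromosome 8. Chromosome 6 carried more H2AK119ub in the knockout library than in the wild-type library, while the rest of the genome carried less. The gain was not restricted to RYBP sites, since without peaks that overlap RYBP the ratio of covered length on chromosome 6 was 2.48 times that of the other autosomes (bootstrap interval over windows 2.13 to 2.90), nor did it rest on a few domains, since the ratio was 1.26 without the 3 windows of largest gain, above the 0.84 of the highest other autosome. Extra copies of chromosome 6 in the knockout clone are a candidate explanation whose prediction was met. Among 342 peaks without RYBP that matched one to one between genotypes, the median ratio of knockout to wild-type width was 1.12 (bootstrap interval 1.08 to 1.16). On the other autosomes this ratio lay between 0.66 and 0.89. Peak width is part of the covered length, so any gain over the whole chromosome would meet the prediction. The result thus does not favour extra copies over other causes. RYBP peaks of the wild type were also wider on chromosome 6, with a median of 1834 bp. On the autosomes other than 6 and 8 it was 1550 to 1651 bp. The 271 RYBP peaks of chromosome 6 that overlap no H2AK119ub peak had a median of 1618 bp, against 1411 to 1503 bp on those autosomes. By this measure, used below for chromosome 8, wild-type chromosome 6 lay above the range too. Wild-type H2AK119ub peaks had 1439 bp against 1234 to 1428 bp. An excess in the knockout clone alone is thus not shown, and whether the wild type shares it is open. A chromosome-wide effect of DDX5 loss itself remains open and was not tested, and input reads, which count copies, were not analysed here.

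Chromosome 8 had the widest peaks in all 3 libraries, and only its first 50 Mb departed from this in the knockout. The median width there was 926 bp in the knockout, near the 999 bp of the median autosome other than 6 and 8, against 1524 bp on the rest of the chromosome, while the wild type had 1561 and 1878 bp and RYBP 1886 and 2092 bp. Larger Polycomb domains on chromosome 8 would leave RYBP sites outside the mark at ordinary width, yet those 256 peaks had a median of 1827 bp (bootstrap interval 1752 to 1886 bp), against 1411 to 1503 bp on the autosomes other than 6 and 8. Extra copies of chromosome 8 predict wider peaks there whatever the mark, which the same 1827 bp meets in the wild type. A gain of chromosome 8 in both lines, without its first 50 Mb in the knockout clone, is a hypothesis these peak widths leave standing. RYBP was not profiled in the knockout, so larger Polycomb domains in that line were not tested by this measure. On the X chromosome, peaks were narrower than on every autosome, with medians of 987 bp, 802 bp and 1314 bp for wild-type H2AK119ub, knockout H2AK119ub and RYBP.

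The fewer and narrower H2AK119ub peaks of the knockout library may reflect lower depth or enrichment in that library, or less of the mark in DDX5-deficient cells. Lower sensitivity alone was set to predict that at least 90% of the widest of the 4 classes of wild-type peaks would be found again, and less than 75% was set to exclude it. The value was 84.6% (83.7% to 85.5%), between the bounds, so the 2 cannot be told apart by this test, and the unknown read depth keeps it open. Peaks with RYBP were retained more often in each of the 4 width classes, by 18.3 points on average. No excess loss of whole peaks at RYBP-bound sites was thus seen. With an overlap of at least 50% of the peak the difference was 23.9 points. The test cannot exclude a loss aimed at RYBP-bound sites, since a peak that lost part of the mark can still count as retained. Peaks with and without RYBP were compared within width classes and not matched on width inside a class. The widest class ran from 2063 to 39824 bp. Nor were the peaks matched on height or on place relative to genes. RYBP was present at 51.6% of genes marked in the wild type alone and at 52.6% of those marked in the knockout alone.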
